A study of Mus musculus with 24 samples.

How the data were processed

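RNA from shock-frozen mouse lung was measured 24 days after irradiation on 24 single-colour Agilent arrays, 2 biological replicates for each of 12 groups. The groups combine no drug, Ly, Imatinib, Su, Ly+Imatinib or Ly+Su with irradiation or none, as the labels name them. Per the labels, total RNA was labelled with Cy3 by linear amplification. The title of the second IR+Su sample numbers it 2 and its source name 1; the title was used. The labels give no strain, dose of irradiation or dose of drug.

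Values came from the files of the individual arrays. Per the file headers, Agilent Feature Extraction 9.1.3.1 made the signals: intensity, background-subtracted and detrended, with low values replaced by a surrogate and no scaling between arrays. The deposited series table holds the same intensity multiplied by a constant and rounded, with ratios to the array files of 0.995 to 1.005 after removal of that constant. Each array file held 43379 spots that were not controls and 1639 controls. Spots of the same probe were averaged, 619 of 41174 probes were dropped because the software marked them as unusable, and 40555 remained. Genes were named from the accession on the array by a table of RefSeq genes for 22951 probes, by symbol for 6659 and by synonym for 3109; 8455 probes kept the name in the file. The probe with the highest mean over all arrays stood for each gene.

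The log2 intensity minus the log2 of each array's 75th percentile was the value analysed, so that changes are relative to that level. A gene was tested when it was well above background, as marked by Feature Extraction, on both arrays of at least 1 group; 20409 of 27670 genes passed, 15271 of them with a gene symbol. Intensities of arrays are not counts, so that no depth can be given; 62.0% to 78.5% of spots per array were well above background. Where a gene was at background in 1 group, a lower bound of the fold was computed against the lowest level marked as well above background.

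Differences were tested with limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8), lmFit and eBayes, with 1 mean per group over all 24 arrays. This leaves 12 residual degrees of freedom, to which the shared variance adds 2.10. P values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold. The comparisons were irradiated against untreated, the mean irradiation difference over the 6 drug arms, each irradiated drug group against IR, each drug alone against untreated, the irradiated combinations against their single agents, and IR+Imatinib against IR+Su. The F test of the 5 differences between irradiation in a drug arm and irradiation without drug gave the interaction. The replicate numbers of different groups were not taken to pair the arrays: over 66 pairs of groups the correlation across genes of deviations from the group means, by replicate number, had a median of 0.036 and a range of -0.202 to 0.251, with 20 pairs over 0.1.

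37 gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. They cover p53 targets, proliferation, collagen and matrix, TGF-beta response, TGF-beta ligands and receptors, the PDGF family and kinases blocked by imatinib, immediate early genes, interferon response, inflammatory cytokines and chemokines, senescence, AhR targets, NRF2 targets, cholesterol and fatty acid synthesis, hypoxia, heat shock and unfolded protein, glucocorticoid response and clock genes. The others mark macrophages, alternative macrophage activation, neutrophils, T and NK cells, B cells, mast cells, thymocytes and lymph node, alveolar type I and type II cells, club cells, ciliated cells, endothelium, fibroblasts, mesothelium, cardiac muscle, skeletal muscle, adipose tissue and erythroid cells, and sex-linked genes. For the irradiation response score, genes past the threshold in the averaged irradiation difference of the other 5 arms were taken, and the mean of the lower genes was subtracted from that of the higher ones on each array.

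The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Among genes with a symbol past the threshold whose arrays did not overlap between groups, or whose 6 arm differences had 1 sign, the rule takes the 12 highest and 12 lowest for both irradiation comparisons, the 10 highest and 10 lowest for irradiated drug groups against IR, and the 5 highest and 5 lowest elsewhere. It takes the 10 smallest p of the interaction, up to 4 members of each list by size of change, and Cdkn1a, Col1a1, Col3a1, Fn1, Acta2, Tgfb1, Tgfbr1, Tgfbr2, Pdgfa, Pdgfb, Pdgfra, Pdgfrb, Kit, Csf1r and Cyp1a1 throughout; 1 further gene fixed with these 15 is not reported. Where under 5 passed, the 5 smallest p are named. Of the list members the text gives a part, chosen for known function after their values were seen. No array was left out of the reported values.

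The alternatives were normexp background correction with an offset of 50 followed by quantile normalization, named by its first step, quantile normalization alone, the series table, no filter, a filter on all 24 arrays, every probe, a replicate block, the groups compared alone, a slide block and leaving out each array. A common floor for low values, slide means, the interaction within and between slides, and leaving out IR 1 in comparisons that do not use it were added later. The slide of each array was read from the deposited files. Recovery was tested on simulated data. Values were drawn at random from each gene's measured mean and its spread as estimated by eBayes, without differences between slides or correlation between genes. Of 50 genes per size changed between irradiated and untreated, limma found 6 at a log2 change of 0.5, 22 at 1, 44 at 2 and 49 at 3.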

Results

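Expression was measured in mouse lung on 24 single-colour arrays, 24 days after irradiation (IR). The labels give 6 drug arms (no drug, Ly, Imatinib, Su, Ly+Imatinib and Ly+Su), each without and with irradiation, which makes 12 groups of 2 biological replicates. The series title names the question: combined inhibition of TGF-beta and PDGF signalling in radiation-induced lung fibrosis. Imatinib is an inhibitor of the ABL, KIT and PDGF receptor kinases. The labels give Ly and Su in short form, and they are used here by those names alone. In all, 20409 genes were tested. The number of arrays, 2 in each group, limits the precision of every value.

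The 24 arrays lay on 6 slides of 4 arrays, and no slide held both irradiated and unirradiated lungs. Untreated and Ly arrays shared slide 1, Imatinib and Su slide 2, and both combinations without irradiation slide 3. IR and IR+Ly arrays shared slide 4, IR+Imatinib and IR+Su slide 5, and both irradiated combinations slide 6. Ly against untreated, IR+Ly against IR, and IR+Imatinib against IR+Su were therefore compared within a slide. In every other comparison of 2 groups, slide and group cannot be told apart. The 75th percentile of the signal was 2478 on array IR 1 and 703 to 1759 on the others. The spike-in probes had a mean log2 signal of 10.04 on IR 1 and 11.41 to 13.23 on the other 23 arrays. IR 1 and IR 2 correlated across genes at r = 0.973, and replicates of the other groups at 0.975 to 0.994; genes are not independent replicates. Arrays IR+Ly+Imatinib 2, IR+Ly+Su 1 and IR+Ly+Su 2 had a lower background, with a median negative control signal of 2.6 to 3.0 against 4.4 to 12.4 on the others. IR+Ly+Imatinib 1 had 330 outlier spots against at most 80 on the others, and its median correlation across genes with the other arrays was 0.964, against 0.958 for IR 1 and 0.975 to 0.986 for the rest. The 12 groups share 1 estimate of the spread: when limma was fitted to the 2 groups compared alone, it called 842 genes between IR+Ly+Su and IR+Ly, 1170 between IR+Ly+Su and IR+Su, and 0 in each of the other 14 comparisons of 2 groups, with 800 to 4516 genes at an unadjusted p under 0.05. Over all comparisons 186 of 629 list tests passed, and 6 with an estimated correlation between genes: heat shock genes in 5 comparisons and glucocorticoid response genes in 1. Values beside genes are log2 differences between group means, ± standard error (SE) where given, with n = 2 arrays in each group. Irradiated drug groups set against IR share the same 2 IR arrays, and drugs alone share the same 2 untreated arrays. Changes that recur from drug to drug in those comparisons are therefore not independent.

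**Figure D1:**
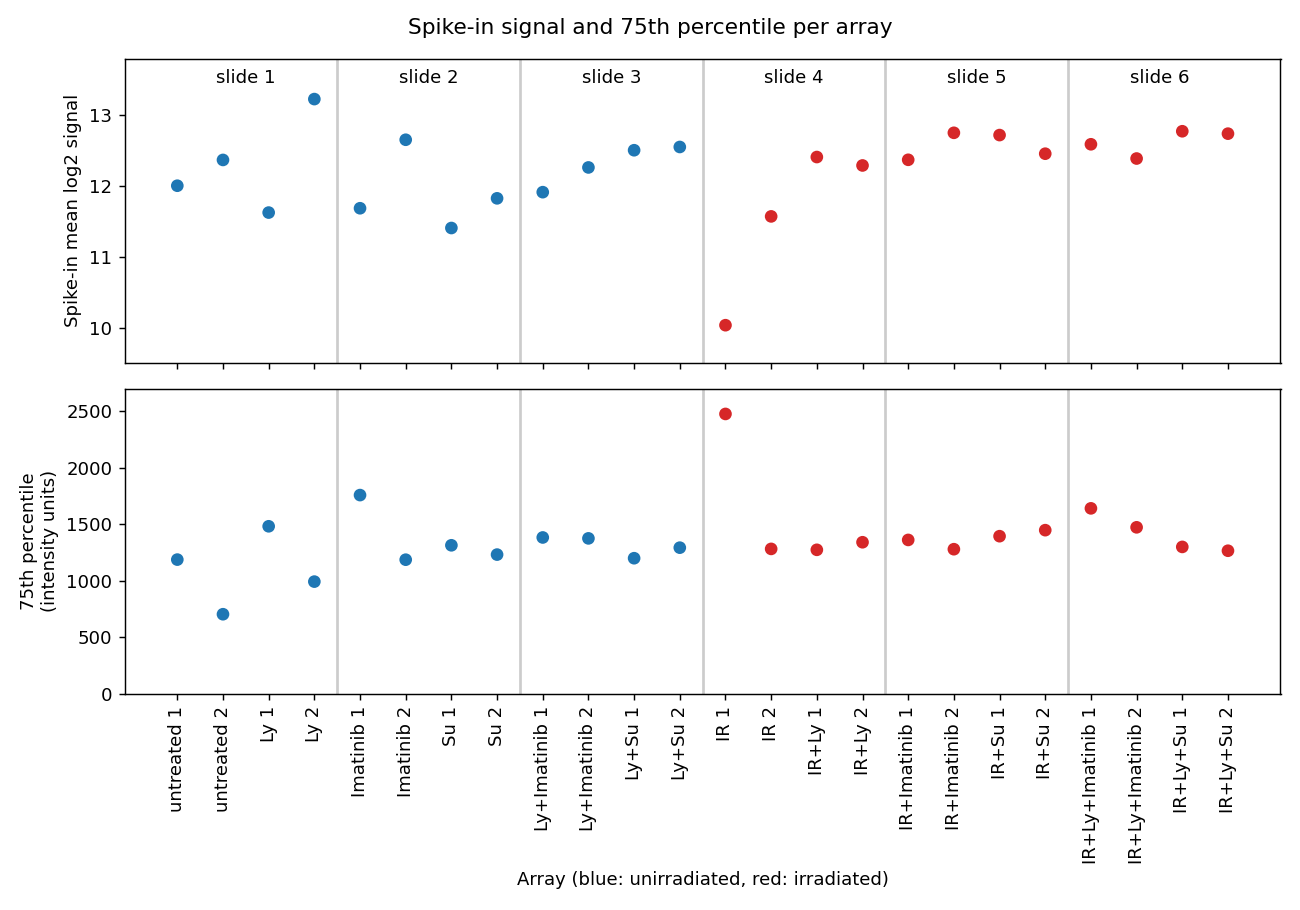
Mean log2 signal of the spike-in probes (upper panel) and 75th percentile of the signal in intensity units (lower panel) for each of the 24 arrays, as points ordered by group with the slide number above. IR 1 has the lowest spike-in signal, 10.04, and the highest 75th percentile, 2478.

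In irradiated lungs without drug, compared with untreated lungs, Mmp12, a macrophage elastase above background on 1 of the 2 untreated arrays, rose by 4.03 ± 0.42. Trem2, a membrane receptor of lipid-handling macrophages, rose by 2.79 ± 0.35, Gpnmb, a membrane glycoprotein of the same cells, 8.55-fold, and Gdf15, a stress cytokine induced by p53, by 2.49 ± 0.30. Col1a1 and Col3a1, which encode fibrillar collagens, rose by 1.51 ± 0.39 and 1.50 ± 0.37, and the matrix protein fibronectin, Fn1, by 1.38. The cell cycle inhibitor Cdkn1a rose by 1.55 ± 0.35 and the receptor Tgfbr2 by 0.63, while the receptor Kit fell (-1.36). Of 15 genes reported in every comparison, 6 changed; the 9 others, among them Acta2, Tgfb1, Tgfbr1 and the PDGF ligands and receptors, did not pass and lay between -1.18 and 0.41. The rises of the largest size were in Chl1, Cpa3, Ankrd34b, Dlk1, Tpsg1, Olfr91, Cma1, Cdhr1, Mup1, Mcpt4, Serpina1d and Pdyn; Chl1 and Cpa3, at background in untreated lungs, were at least 27.2-fold and 50.9-fold higher, and 9.04-fold and 16.5-fold without IR 1. Those of the falls were in Eppin, Apol11b, Tnn, Nmrk2, Caskin1, Cst8, Adra2c, Zfp652, Per1, Glp1r, Grp and Alas2; Eppin, at background with irradiation, was at least 6.10-fold lower. Tnn, Caskin1 and Adra2c were at -1.18, -0.92 and -1.16 without untreated 2 and -5.00, -4.90 and -4.34 without untreated 1, and Zfp652 and Glp1r at -1.25 and -0.84 without IR 1 and -4.02 and -4.34 without IR 2. In all, 1460 genes were higher and 1415 lower, and with every probe tested 1841 and 2052. Without IR 1 these were 110 and 51, and the count was 8631 without IR 2, 949 without untreated 1 and 622 without untreated 2, with 6843 genes at an unadjusted p under 0.05 on all arrays. Mmp12, Gpnmb, Trem2 and Gdf15 kept an adjusted p of 0.00563, 0.00738, 0.0131 and 0.0138 without IR 1; Col1a1, Col3a1, Fn1, Cdkn1a, Tgfbr2 and Kit had 0.251, 0.230, 0.278, 0.186, 0.149 and 0.186. Of the 44 genes named that passed, 8 kept their call whichever array of the groups compared was left out (Ankrd34b, Clec10a, Gdf15, Gpnmb, Mmp12, Psrc1, Thbs2 and Trem2).

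By gene list in the same comparison, 18 of 27 measured inflammatory cytokines and chemokines rose (19 when adjusted over the list alone), with Saa3 at 4.17 and Ccl8 at 3.89; Il6, at background in untreated lungs, was at least 3.98-fold higher, and 2.07-fold without IR 1. The list's adjusted p was 2.11e-09, and 0.374 with an estimated correlation between genes. Of 39 collagen and matrix genes 14 rose (22 adjusted over the list alone), among them Timp1 (2.96), Tnc (2.90) and Thbs2, at background in untreated lungs and at least 4.80-fold higher; the list's adjusted p was 2.11e-09, and 0.452 with an estimated correlation. Without IR 1, 3 members rose and the list's adjusted p was 1.35e-09. Macrophage and monocyte markers rose in 14 of 29 cases (17 adjusted over the list alone; adjusted p = 8.05e-08, and 0.374 with an estimated correlation). Of 29 p53 targets 10 rose (11 adjusted over the list alone), with Psrc1 at 2.55 and Eda2r at 2.00 (adjusted p = 0.000118, and 0.452 with an estimated correlation). Senescence genes rose in 10 of 21 cases (1 fell), interferon response genes in 8 of 32, TGF-beta response genes in 5 of 32 (1 fell) and alternative macrophage activation genes, such as Clec10a at 1.41, in 6 of 16. The adjusted p of these lists was 1.04e-05, 0.00128, 0.00346 and 0.00378, and 0.374, 0.452, 0.452 and 0.45 with an estimated correlation. Endothelial markers fell in 11 of 28 cases, with Lyve1 at -1.26 (adjusted p = 2.76e-05, and 0.466 with an estimated correlation), and clock genes in 6 of 17, with Per1 at -2.63 (adjusted p = 0.00725, 0.45 with an estimated correlation and 0.0551 without IR 1). The proliferation list had 3 of 30 members higher (12 adjusted over the list alone; adjusted p = 3.86e-06, 0.688 with an estimated correlation and 0.0574 without IR 1). Of 7 mast cell markers 4 rose, with Cma1 at 4.81 and Mcpt4 at 4.57 (adjusted p = 0.0207, and 0.452 with an estimated correlation); Cpa3 had an adjusted p of 0.0582 without IR 1. Without IR 1, members past the threshold numbered 2 in the macrophage list, 3 in the p53 list, 2 in the senescence list and 1 in the alternative macrophage list, and 0 passed in limma in the inflammatory, interferon, TGF-beta response, endothelial, clock, proliferation and mast cell lists (16, 10, 7, 8, 3, 2 and 3 at an unadjusted p under 0.05). The mast cell list mean was 0.36 on IR 1, -2.24 on IR 2 and -3.72 in the untreated group, and 1 of its 7 measured markers fell. Saa3, Timp1, Tnc, Per1, Cma1 and Mcpt4 were at 3.07, 2.00, 2.08, -1.70, 3.26 and 2.75 without IR 1 and 5.26, 3.93, 3.72, -3.55, 6.36 and 6.38 without IR 2. Leaving out single arrays other than IR 1 put the adjusted p of these lists past 0.05: TGF-beta response 0.200 without IR 2 and 0.0619 without untreated 1, alternative macrophage activation 0.0663 without IR 2, interferon response 0.0578 without IR 2 and 0.174 without untreated 1 and mast cells 0.0501 without IR 2 and 0.0619 without untreated 1.

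Averaged over the 6 arms, 12 irradiated arrays against 12 unirradiated ones, 3441 of the 20409 genes tested rose and 3213 fell. Which direction held more genes varied with the setting: 2652 rose and 3405 fell with quantile normalization, 2508 and 3376 with normexp background correction, 3350 and 4763 with no filter on background, 2418 and 3256 on genes above background on all 24 arrays and 5224 and 3824 with every probe tested. The p53 targets Gdf15, Psrc1, Eda2r and Cdkn1a rose by 1.72 ± 0.12, 1.60 ± 0.13, 1.39 ± 0.14 and 1.07 ± 0.14. Of 39 collagen and matrix genes 32 rose, both over all genes and adjusted over the list alone, with Tnc at 1.89 ± 0.25, Thbs2 at 1.53 and Eln at 1.42; Col1a1, Col3a1 and Fn1 rose by 0.98 ± 0.16, 0.78 and 0.94. Tgfbr1 rose by 0.27 and Tgfbr2 by 0.27, while Kit fell (-0.69). Proliferation genes rose in 25 of 30 cases (26 adjusted over the list alone), among them Cdk1 (1.30). Inflammatory genes rose in 14 of 27 cases (1 fell), with Ccl8 at 1.98, macrophage markers in 13 of 29, senescence genes in 14 of 21 (2 fell), p53 targets in 11 of 29 (4 fell) and TGF-beta response genes, such as Inhba (1.18) and Itgb6 (0.87), in 13 of 32 (2 fell). Ciliated cell markers fell in 16 of 22 cases, with Tppp3 at -0.59, T and NK cell markers in 10 of 32, with Cd8b1 at -0.71, endothelial markers in 11 of 28 (2 rose), mesothelial markers in 6 of 14 and heat shock genes in 6 of 15 (1 rose), with Hspb1 at -0.53. The highest rises with the same sign in all 6 arms were in Dlk1, Ankrd34b, Tfap2e, Kng1, Serpina1d, Cpa3, Gdf6, Aadac, Mcpt4, Cldn2, Cdhr1 and Col2a1, and the lowest falls in Eppin, Grp, Olfr1056, Asprv1, Adam18, Tcap, Rspo3, Cst8, Dusp26, Myom2, Olfr1284 and Gprc6a. Dlk1 was above background on 12 irradiated and 0 unirradiated arrays, and Ankrd34b, Kng1, Gdf6 and Aadac on 9 to 12 and 0. Eppin and Gprc6a were above background on 8 of the 12 irradiated arrays, Adam18 on 5, and Olfr1056, Rspo3 and Olfr1284 on 1, so that background limits the size of these falls.

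For the averaged comparison the adjusted p was 3.71e-11 for the collagen list, 1.42e-10 for proliferation, 0.000275 for inflammation, 0.000269 for macrophages, 6.23e-05 for senescence, 0.0249 for p53 targets and 0.00889 for TGF-beta response. For the lists that fell it was 1.32e-08 for ciliated cells, 0.0047 for T and NK cells, 0.0047 for mesothelial cells, 0.00918 for heat shock and 0.0192 for endothelial cells. With an estimated correlation the adjusted p of these 12 lists lay between 0.563 and 0.697. Of the 15 genes reported in every comparison 7 changed, and the 8 others lay between -0.65 and 0.13; of the Pdgfra probes, 1 not used in the tests was called in the opposite direction to the one tested. Without IR 1, 3837 genes were higher and 3906 lower, of which 6356 were called in the same direction with all arrays; the endothelial list had an adjusted p of 0.0752. With slide as a block (consensus correlation 0.142) 3233 genes passed, with adjusted p = 2.58e-12 for the collagen list and 1.86e-12 for proliferation. On slide means, 3 slides against 3, 1 gene passed. No slide holds both conditions, so that no value within a slide can be given and slide and irradiation cannot be told apart. Among the 44 named genes that passed, 42 kept their call whichever array of the groups compared was left out. The p53 list had an adjusted p of 0.0616 without Ly 2 and 0.0578 without IR+Ly+Imatinib 2.

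**Figure D2:**
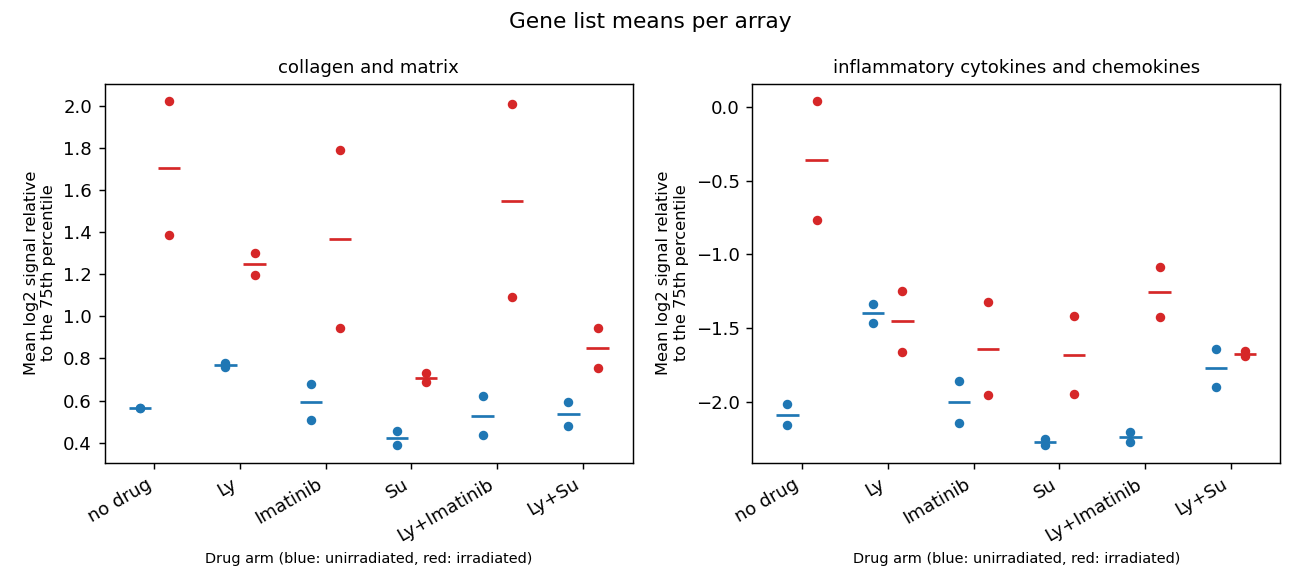
Mean log2 signal, relative to each array's 75th percentile, of the collagen and matrix list (left) and of the inflammatory cytokine and chemokine list (right) on each array (points) with the mean of each group (bars), for unirradiated and irradiated lungs in the 6 drug arms. The IR arrays have the 2 highest inflammatory means; the irradiated minus unirradiated difference of the collagen list runs from 0.29 in the Su arm to 1.14 without drug.

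Ly added to irradiation, compared within slide 4 with irradiation alone, went with lower Spp1, the secreted matrix protein osteopontin, at -2.59 ± 0.27 (adjusted p = 0.00151, and 0.00847 without IR 1). The chemokine Cxcl1 (-2.42), Mmp12 (-2.10) and Gpnmb (-1.95) fell as well. Pax5, a transcription factor of B cells, rose by 1.77, the lymphoid chemokine Ccl21c by 1.82 and Hgf, hepatocyte growth factor, by 1.42. The other large rises were in Dusp15, Znrf4, Siglecg, Vmn1r212, Elmo1 and Zbed3, and the other large falls in Orm2, Gzmc, Serpina3k, Lhx2, Cfi and Sectm1b. Of 27 inflammatory genes 1 fell (13 adjusted over the list alone; adjusted p = 7.39e-06, and 0.529 with an estimated correlation). Of 23 B cell genes 2 rose (10 adjusted over the list alone; adjusted p = 2.83e-05, and 0.529 with an estimated correlation). Collagen and matrix genes fell in 2 of 39 cases (3 adjusted over the list alone; adjusted p = 0.0253, 0.812 with an estimated correlation and 0.352 without IR 1). The macrophage, senescence, interferon, p53, NRF2, ciliated cell and alternative macrophage lists were also lower, each with at most 2 members lower past the threshold over all genes and adjusted p from 0.00102 to 0.0255, and 0.529 to 0.717 with an estimated correlation. None of the 15 genes reported in every comparison passed in limma; they lay between -0.70 and 1.16. In all 133 genes were higher and 55 lower, and 12 and 21 without IR 1, 8 of them the same genes. The count was 7769 without IR 2, 15 without IR+Ly 1 and 51 without IR+Ly 2. With quantile normalization 54 were higher and 42 lower, and with normexp background correction 59 and 83. Mmp12, Gpnmb and Cxcl1 had adjusted p of 0.184, 0.182 and 0.242 without IR 1. Gpnmb was at -1.29 without IR+Ly 1 and -2.61 without IR+Ly 2. Without IR 1, members past the threshold numbered 1 in the collagen list, and 0 passed in limma in the inflammatory and B cell lists (4 and 12 at an unadjusted p under 0.05). Taking the 19 named genes past the threshold, Spp1 kept its call whichever array of the groups compared was left out. Lists that lost their call without another array were alternative macrophage activation 0.167 without IR 2 and 0.344 without IR+Ly 1, ciliated cells 0.174 without IR 2 and 0.224 without IR+Ly 2, collagen and matrix 0.249 without IR+Ly 1, macrophages and monocytes 0.0514 without IR 2 and 0.352 without IR+Ly 1 and senescence 0.0580 without IR+Ly 1.

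Imatinib added to irradiation was accompanied by higher Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, than irradiation alone (5.38 ± 0.66; adjusted p = 0.000755, and 0.0124 without IR 1). Its difference was 3.90 without IR+Imatinib 1 and 6.85 without IR+Imatinib 2. Spp1 fell (-2.71 ± 0.27; adjusted p = 0.00257 without IR 1), Mmp12 was lower at -2.21 and Clec10a, a lectin of alternatively activated macrophages, at -1.22. Pax5 rose by 1.75 and Kit by 1.10 (adjusted p = 0.372 without IR 1). Of 15 heat shock and unfolded protein genes 10 fell, 11 when adjusted over the list alone (adjusted p = 4.82e-06, 0.19 with an estimated correlation and 8.86e-09 without IR 1). Inflammatory genes fell in 9 of 27 cases (15 adjusted over the list alone), interferon response genes in 8 of 32, macrophage markers in 5 of 29 (1 rose), p53 targets in 4 of 29, NRF2 targets in 4 of 22 and hypoxia genes in 3 of 15. Their adjusted p was 1.63e-06, 0.000175, 0.00027, 0.000611, 0.00485 and 0.00707, and 0.409 to 0.422 with an estimated correlation. Without IR 1, members past the threshold numbered 1 in the heat shock list, and 0 passed in limma in the inflammatory, interferon, macrophage, p53, NRF2 and hypoxia lists (9, 8, 2, 4, 6 and 3 at an unadjusted p under 0.05). The collagen list was not shifted past the threshold (1 higher and 3 lower of 39; adjusted p = 0.177). The other large rises were in Slc35f4, Spertl, Olfr1012, Scn11a, Syt17, Sval1, Olfr1205, Tfap2e and Eppin, most of them at background on the IR arrays, and the largest falls in Saa3 (-3.98), Mup1, Chl1, Cdhr1, Pnoc, Saa2, Taar2, Orm2 and Serpinb12. Saa3 was at -2.89 without IR 1 and -5.08 without IR 2. Of the 15 genes reported throughout 2 rose, and the 13 others lay between -0.83 and 1.22. In all 1656 genes were higher and 1039 lower, and 221 and 53 without IR 1. The count was 9052 without IR 2, 1075 without IR+Imatinib 1 and 379 without IR+Imatinib 2. With quantile normalization 510 were higher and 513 lower, and with normexp background correction 497 and 573. Of the 24 genes named that passed, 7 kept their call whichever array of the groups compared was left out (Clec10a, Cyp1a1, Olfr1012, Pax5, Pnoc, Spertl and Spp1). Without IR+Imatinib 2 the collagen list was lower (mean -0.76; adjusted p = 0.00024). The adjusted p of the NRF2 list was 0.0548 without IR 2 and 0.0599 without IR+Imatinib 2.

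With Su added to irradiation, Spp1 was lower than with irradiation alone (-3.47 ± 0.27; adjusted p = 1.81e-05, and 0.000415 without IR 1), as did Mmp12 (-2.72), Gpnmb (-2.26), Trem2 (-2.21) and the monocyte chemokine Ccl2 (-3.11), with adjusted p of 0.0115, 0.0130, 0.0119 and 0.0159 without IR 1. Pax5 rose by 2.73 ± 0.32 and Bank1, a B cell scaffold protein, by 1.99. Of 39 collagen and matrix genes 15 fell (19 adjusted over the list alone), with Timp1 at -3.04, Col3a1 at -1.46 and Col1a1 at -1.22; the list had adjusted p = 4.99e-05, 0.545 with an estimated correlation and 0.000875 without IR 1. Of 15 heat shock genes 12 fell (13 adjusted over the list alone), among them Hsph1 (-1.66), Hspa1a (-1.52) and Hspb1 (-1.16), with adjusted p = 1e-07, and 0.0723 with an estimated correlation. B cell genes rose in 14 of 23 cases and fell in 1 (adjusted p = 1.69e-06, and 0.494 with an estimated correlation). Falls were counted in 15 of 29 p53 targets, with Gdf15 at -1.93, 17 of 29 macrophage markers, 14 of 21 senescence genes, 14 of 27 inflammatory genes, 9 of 32 TGF-beta response genes and 7 of 21 cholesterol synthesis genes. In each of these lists except the inflammatory list, 1 gene rose. The adjusted p of these lists was 2.76e-05, 0.000856, 0.000242, 0.000151, 0.011 and 0.0332, and 0.405 to 0.545 with an estimated correlation. Without IR 1, members past the threshold numbered 3 in the collagen list, 9 in the heat shock list, 13 in the B cell list, 6 in the p53 list, 3 in the macrophage list, 3 in the senescence list, 6 in the inflammatory list, 3 in the TGF-beta response list and 3 in the cholesterol list. Cdkn1a (-1.67) and Tgfbr2 (-0.42) were lower and Cyp1a1 (2.60) and Kit (0.90) higher, which makes 6 of the 15 genes reported throughout with Col1a1 and Col3a1; the 9 others lay between -1.03 and 1.12. Without IR 1 the adjusted p was 0.289 for Col1a1, 0.148 for Col3a1, 0.0737 for Cdkn1a, 0.448 for Tgfbr2, 0.127 for Cyp1a1 and 0.517 for Kit. Nxpe3, Carns1, Olfr970, Ttc6, Tnfsf12, Tfap2e, Glp1r and Gabre had the other largest rises, and Tpsg1, at background with IR+Su and at least 11.4-fold lower (5.04-fold without IR 1), Chl1, Ankrd34b, Saa3, Pdyn, Cpa3, Mup1, Mcpt4, Saa2 and Cma1 the largest falls; the mast cell genes Cpa3, Mcpt4 and Cma1 had adjusted p of 0.128, 0.0966 and 0.117 without IR 1. In all 2228 genes were higher and 3061 lower, and 692 and 813 without IR 1. Ccl2, Timp1 and Glp1r were at -2.52, -2.08 and 0.89 without IR 1 and -3.71, -4.01 and 4.39 without IR 2. The count was 9536 without IR 2, 1862 without IR+Su 1 and 1519 without IR+Su 2. With every probe tested 3893 were higher and 3746 lower. Among the 36 named genes that passed, 18 kept their call whichever array of the groups compared was left out (Ankrd34b, Bank1, Carns1, Ccl2, Gdf15, Gpnmb, Hspa1a, Hspb1, Hsph1, Mmp12, Pax5, Pdyn, Saa3, Spp1, Timp1, Tnfsf12, Trem2 and Ttc6). Lists that lost their call were TGF-beta response 0.185 without IR 2 and cholesterol synthesis 0.534 without IR 2 and 0.0807 without IR+Su 2.

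With Ly+Imatinib added to irradiation, 13 of 15 heat shock genes fell, with Hsph1 at -1.15, Hspa1a at -1.24 and Hspb1 at -0.86 (adjusted p = 6.92e-08, 0.0673 with an estimated correlation and 5.28e-10 without IR 1). Spp1 fell (-2.70 ± 0.27; adjusted p = 0.00157 without IR 1), and Cyp1a1 rose by 3.55 ± 0.66 (adjusted p = 0.0414 without IR 1). Top2a, a marker of dividing cells, rose by 1.43; of 30 proliferation genes 5 rose (4 adjusted over the list alone; adjusted p = 0.000468, and 0.782 with an estimated correlation). Fabp4, a fatty acid carrier of adipocytes, was at -1.71, with 6 of 12 adipose genes lower (adjusted p = 0.000818, and 0.411 with an estimated correlation). Inflammatory genes fell in 10 of 27 cases, macrophage markers in 8 of 29, NRF2 targets in 8 of 22, p53 targets in 7 of 29 and ciliated cell markers in 7 of 22. Their adjusted p was 0.000265, 0.000268, 5.57e-05, 0.000206 and 0.000268, and 0.312 to 0.656 with an estimated correlation. Without IR 1, members past the threshold numbered 7 in the heat shock list, 23 in the proliferation list, 1 in the adipose list, 2 in the NRF2 list, 3 in the p53 list and 1 in the ciliated cell list, and 0 passed in limma in the inflammatory and macrophage lists (6 and 4 at an unadjusted p under 0.05). The collagen list had 2 members higher and 3 lower of 39 and was not shifted past the threshold (adjusted p = 0.461). Of the 15 genes reported throughout 2 passed, Cyp1a1 and Kit, at 1.16; the 13 others lay between -0.86 and 0.24. Among the largest rises on all arrays were those of Tfap2e, Eya4 and Foxq1, beside Cyp1a1, and among the largest falls those of Mup1, Mc5r, Nutm1, Suv39h2, Saa3, Gpr37, Olfr955, Olfr1472 and Olfr888. The rises of Olfr154, Ccdc3, Olfr26, Trim67, Trpv3 and Trh rested on IR+Ly+Imatinib 1, the array with 330 outlier spots: they were at 1.47, 1.88, 0.98, 1.02, 1.31 and 0.71 without it (adjusted p of 0.166 to 0.398) and 6.86, 5.71, 6.50, 6.26, 5.65 and 6.08 without IR+Ly+Imatinib 2. The fall of Mpeg1, a macrophage gene, rested on the same array, at -0.75 without it (adjusted p = 0.128) and -6.02 without IR+Ly+Imatinib 2. In all 2313 genes were higher and 1576 lower, and 969 and 387 without IR 1. The count was 8977 without IR 2, 1345 without IR+Ly+Imatinib 1 and 1859 without IR+Ly+Imatinib 2. With quantile normalization 893 were higher and 1015 lower, and with normexp background correction 833 and 1097. Taking the 27 named genes past the threshold, 11 kept their call whichever array of the groups compared was left out (Cyp1a1, Fabp4, Foxq1, Gpr37, Hspb1, Hsph1, Olfr1472, Olfr888, Olfr955, Spp1 and Tfap2e). Lists that lost their call were ciliated cells 0.126 without IR+Ly+Imatinib 1 and proliferation 0.997 without IR 2 and 0.159 without IR+Ly+Imatinib 1, and the collagen list was lower without IR+Ly+Imatinib 1 (mean -0.61; adjusted p = 0.000769).

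Ly+Su added to irradiation gave 3266 higher and 2453 lower genes than irradiation alone. Spp1 fell (-3.20 ± 0.27; adjusted p = 0.000407 without IR 1), as did Mmp12 (-2.80), Gpnmb (-2.15), Trem2 (-2.09) and Ccl2 (-2.82). Hspa5, a chaperone of the endoplasmic reticulum, was at -1.04 and Hsph1 at -1.18, and 12 of 15 heat shock genes were lower (adjusted p = 3.85e-07, and 0.0947 with an estimated correlation). B cell genes rose in 14 of 23 cases, with Pax5 at 2.63 (adjusted p = 0.000403, and 0.594 with an estimated correlation). Of 39 collagen and matrix genes 9 fell (adjusted p = 3.72e-05, 0.594 with an estimated correlation and 0.00074 without IR 1), Col3a1 among them (-1.09). Among p53 targets 15 of 29 fell, with Gdf15 at -1.52; falls were also counted in 17 of 29 macrophage markers, 13 of 27 inflammatory genes, 7 of 15 hypoxia genes and 5 of 14 glucocorticoid response genes. The adjusted p was 4.56e-06, 9.04e-06, 4.56e-06, 0.0012 and 0.016, and 0.237 to 0.474 with an estimated correlation. Without IR 1, members past the threshold numbered 8 in the heat shock list, 13 in the B cell list, 2 in the collagen list, 6 in the p53 list, 2 in the macrophage list, 7 in the inflammatory list and 2 in the glucocorticoid list, and 0 passed in limma in the hypoxia list (4 at an unadjusted p under 0.05). Cdkn1a (-1.48) was lower and Cyp1a1 (2.07) and Kit (0.92) higher, which with Col3a1 makes 4 of the 15 genes reported throughout; the 11 others lay between -0.90 and 1.20. Without IR 1 these 4 had adjusted p of 0.110, 0.238, 0.457 and 0.332. The largest rises were in Lalba, Eya4, Tnfsf12, Olfr1316, Ipw, Olfr1232, Olfr64, Tfap2e, Olfr1317 and Prl3a1, and the largest falls in Jakmip3, Chl1, Saa3, Suv39h2, Nutm1, Olfr955, Saa4, Mup1, Mc5r and Olfr888. Without IR 1, 1342 genes were higher and 556 lower, and the count was 10006 without IR 2, 1508 without IR+Ly+Su 1 and 2148 without IR+Ly+Su 2. Ccl2 was at -2.23 without IR 1 and -3.41 without IR 2. Of the higher genes 1011 were above background on both IR+Ly+Su arrays and on no IR array. With quantile normalization 2064 were higher and 1711 lower, with normexp background correction 1887 and 1889, and with no filter on background 3430 and 4690. Of the 33 genes named that passed, 16 kept their call whichever array of the groups compared was left out (Ccl2, Gpnmb, Hspa5, Hsph1, Mmp12, Olfr1232, Olfr1316, Olfr1317, Olfr888, Olfr955, Pax5, Prl3a1, Saa3, Spp1, Tnfsf12 and Trem2). The glucocorticoid list had an adjusted p of 0.169 without IR 2.

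**Figure D3:**
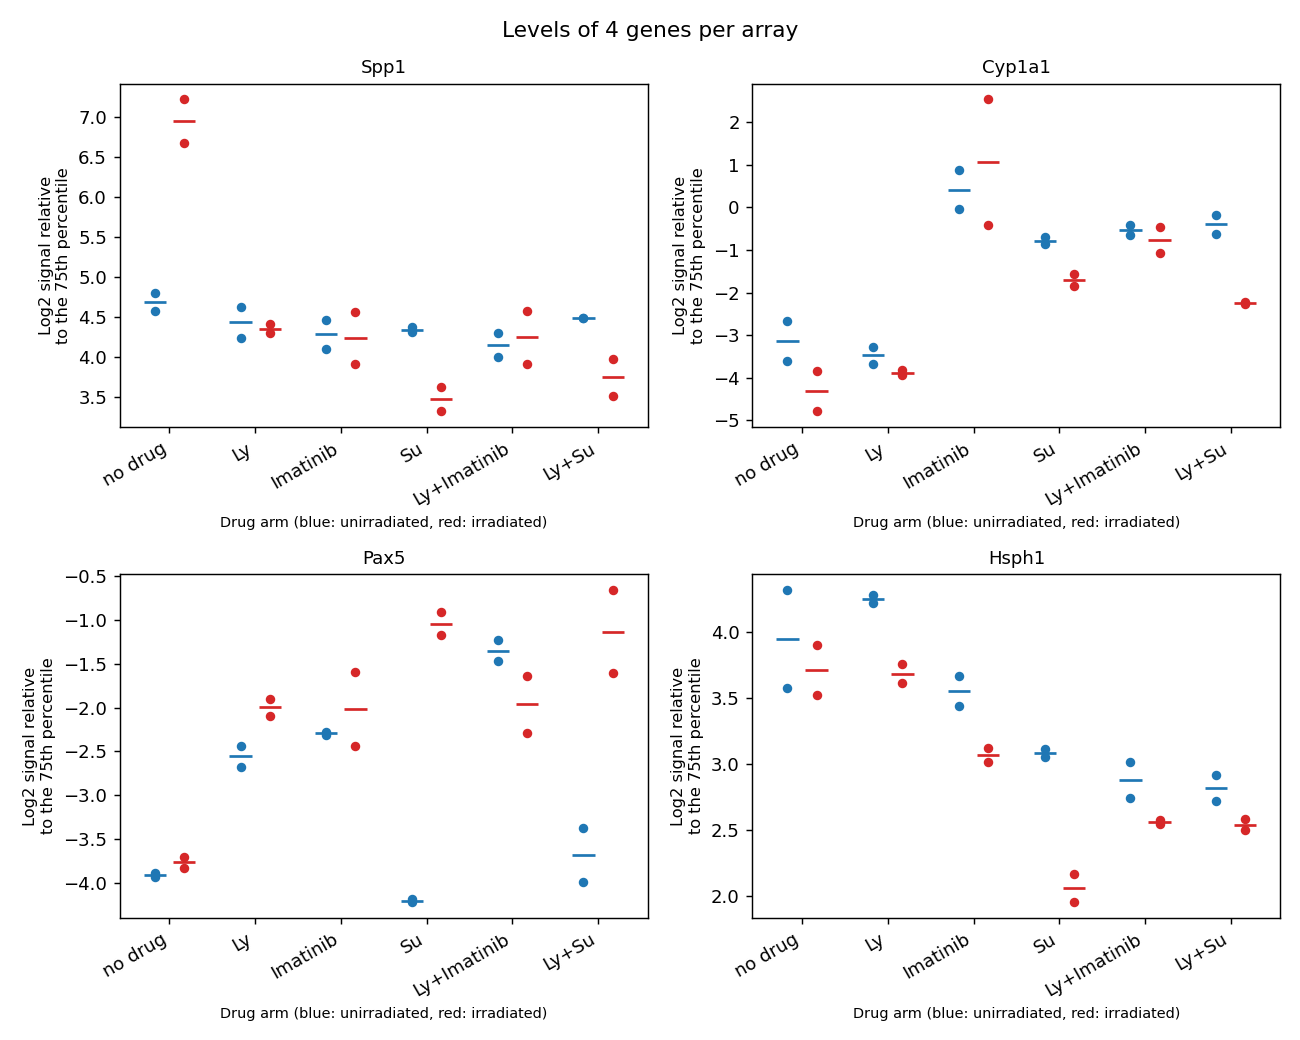
Log2 signal relative to each array's 75th percentile for Spp1, Cyp1a1, Pax5 and Hsph1 on each array (points) with the mean of each group (bars), for unirradiated and irradiated lungs in the 6 drug arms. Spp1 is lower and Pax5 higher on the arrays of each irradiated drug group than on the IR arrays.

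The difference between arms in how irradiation shifted the collagen list was tested with camera. The collagen and matrix mean was 1.14 higher in irradiated than in unirradiated lungs without drug, 0.48 with Ly, 0.77 with Imatinib, 0.29 with Su, 1.02 with Ly+Imatinib and 0.31 with Ly+Su. The smaller shift than without drug had adjusted p = 0.00076 for Ly, 0.00874 for Su and 0.000823 for Ly+Su, and 0.734, 0.871 and 0.861 with an estimated correlation; for Imatinib and Ly+Imatinib it was 0.159 and 0.662. The inflammatory list shifted by 1.72 without drug, -0.05 with Ly, 0.36 with Imatinib, 0.59 with Su, 0.98 with Ly+Imatinib and 0.10 with Ly+Su. That difference between arms had adjusted p = 1.61e-14, 3.5e-07, 0.00874, 0.00331 and 4.12e-07 for the drug arms in turn. With an estimated correlation it was 0.222, 0.694, 0.871, 0.876 and 0.85. The macrophage list differed in the same way for Ly, Imatinib, Ly+Imatinib and Ly+Su, with adjusted p = 1.39e-10, 0.000345, 0.000741 and 0.000293, and 0.248, 0.694, 0.876 and 0.85 with an estimated correlation. Without irradiation the inflammatory mean was -1.40 with Ly, -1.77 with Ly+Su and -2.09 without drug, and the macrophage mean 1.54 with Ly against 1.03. The collagen list was 0.20 higher with Ly (adjusted p = 0.0456, 0.833 with an estimated correlation), not with Su or Ly+Su. Part of these smaller shifts lies in unirradiated arrays. Without IR 1 the adjusted p of the inflammatory list was 0.0512 for Ly+Imatinib. Over 185 such tests of 37 lists in 5 arms, 39 passed, and 0 with an estimated correlation. All 5 arms were set against the same IR and untreated arrays, so that tests of a list are not independent. IR 1 stood above IR 2 by 0.64 in the collagen and 0.81 in the inflammatory list.

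Gene by gene, the irradiation difference varied between the arms for 220 genes, and for 236 without IR 1, of which 156 were the same genes. Rab27a, a GTPase of vesicle secretion, changed with irradiation by 2.14 in the Su arm and 2.45 in the Ly+Su arm, and by -0.16 to 0.37 in the other arms, with adjusted p = 0.000251. Without irradiation Rab27a was at -2.60 with Ly+Su against untreated lungs, so that its 2.45 in that arm lies mostly in low unirradiated arrays. Cep20, a centrosome gene, differed by 2.22 to 2.83 in the Imatinib, Su and both combination arms against -0.21 without drug and 0.10 with Ly (adjusted p = 0.000151). The cytokine Tnfsf12 differed in the same arms by 2.37 to 3.09 against -0.38 and 0.17 (adjusted p = 0.000186). These genes were above background on 8 and 6 of the 24 arrays, so that background limits the size of their differences. The no drug and Ly arms share slides 1 and 4, so that for both genes drug and slide cannot be told apart. C1s2, a complement protease, had an adjusted p of 0.000191. The next smallest adjusted p were those of Itga10 (0.000251), Spertl (0.000421), Tlx2 (0.000421), Kcne3 (0.000684), Mc4r (0.00188) and Slc45a1 (0.00196). C1s2, Itga10 and Spertl were above background on 10, 7 and 2 arrays. In tests confined to arms that share slides 22 genes passed, Itga10, C1s2, Rab27a and Pax5 among them. Their adjusted p was 0.00034, 0.000369, 0.0015 and 0.00657. The irradiation difference of Pax5 was 2.88 higher in the Su than the Imatinib arm and 3.17 higher with Ly+Su than Ly+Imatinib. Pax5 was chosen after its values were seen. Its log2 level in unirradiated lungs was -4.20 with Su, -2.29 with Imatinib, -3.68 with Ly+Su and -1.35 with Ly+Imatinib. In irradiated lungs it was, in turn, -1.04, -2.01, -1.13 and -1.96. Much of the Pax5 difference therefore lies in the unirradiated arrays. Cep20, Tnfsf12, Tlx2, Kcne3, Mc4r and Slc45a1 did not pass in the tests within slides. Between the pairs of slides, 533 genes passed. The count of 220 was 5416 without IR 2, 405 without IR+Imatinib 1, 142 without IR+Ly 1, 667 without IR+Ly+Imatinib 2, 98 without IR+Ly+Su 1, 101 without IR+Ly+Su 2, 127 without IR+Su 1, 98 without IR+Su 2, 348 without Ly 1, 113 without Ly+Imatinib 1, 137 without Ly+Imatinib 2, 106 without Su 1, 114 without Su 2 and 130 without untreated 2. On genes above background on all 24 arrays 112 passed, with normexp background correction 98 and with quantile normalization 120.

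An irradiation response score took, for each arm, the genes changed by irradiation in the other 5 arms. Irradiated minus unirradiated, it was 0.43 without drug, 0.34 with Ly, 0.91 with Imatinib, 0.82 with Su, 1.07 with Ly+Imatinib and 0.85 with Ly+Su, in log2 units. The genes differed from arm to arm, so that the values are not on a single scale, and the score has no test. The arms with 0.43 and 0.34 share slides 1 and 4 and the others lie elsewhere, so that slide and drug cannot be told apart. With normexp background correction and quantile normalization together it was 0.57, 0.48, 0.75 and 0.51 for the last 4 arms, and with quantile normalization alone 0.80, 0.70, 1.08 and 0.76.

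**Figure D4:**
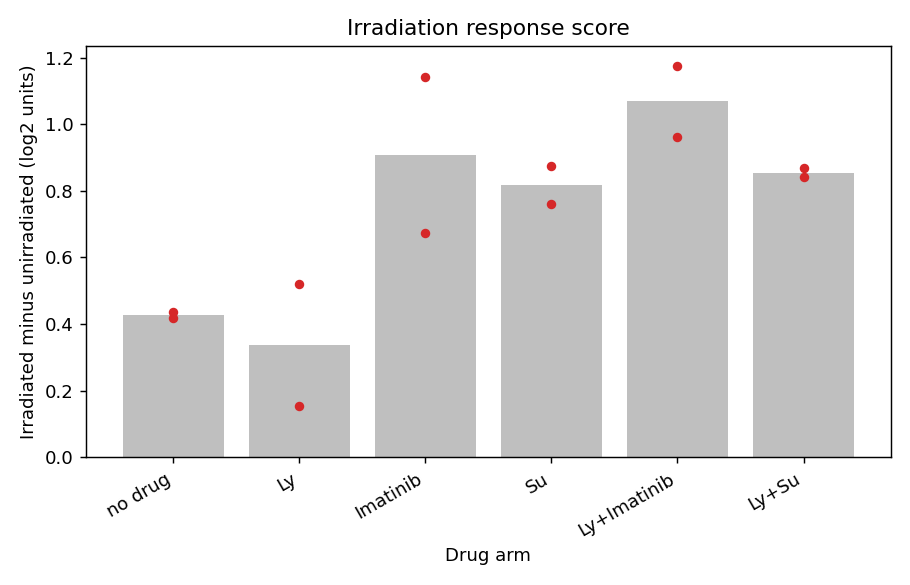
Irradiation response score, irradiated minus unirradiated, in log2 units for the 6 drug arms as bars of group mean differences, with the difference of each irradiated array from the unirradiated group mean as points. The bars run from 0.34 with Ly to 1.07 with Ly+Imatinib.

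Ly alone, compared within slide 1 with untreated lungs, changed 1 gene, which has no gene symbol, in limma (1164 at an unadjusted p under 0.05); without IR 1, 4 were higher and 1 lower. The genes with the smallest p, none of which passed, were Kif15 (adjusted p = 0.0625), Olfr888, Gpr34 (2.04), Nmrk2 and Tm4sf4 (-1.18). Kif15, at background in untreated lungs, was at least 2.07-fold higher, and Olfr888 and Nmrk2, at background with Ly, at least 3.86-fold and 3.58-fold lower. Gpr34 was above background on 1 untreated array and Tm4sf4 on 1 Ly array, and Gpr34 was at 1.25 without untreated 1 and 2.83 without untreated 2. Lists of inflammatory, macrophage, B cell, T and NK cell, neutrophil and lymph node genes were higher, with adjusted p = 1.98e-09, 9.4e-09, 1.24e-09, 1.39e-06, 0.000391 and 0.00263, and 0.216 to 0.587 with an estimated correlation. Ciliated cell, cardiac muscle, club cell and alveolar type I cell genes were lower, with adjusted p = 6.05e-08, 5.96e-08, 9.55e-06 and 7.1e-05, and 0.216 to 0.431 with an estimated correlation. No member of these lists passed over all genes. The count was 19 without Ly 1, 0 without Ly 2, 33 without untreated 1 and 38 without untreated 2. It was 8 with quantile normalization, 4 of them higher, and 6 with normexp background correction. Without Ly 1 the neutrophil list was lower, with a mean of -0.79 (adjusted p = 0.0098), and without untreated 1 its adjusted p was 0.0596; the club cell list had 0.267 without Ly 1 and 0.0536 without untreated 2, and the lymph node list 0.268 without Ly 2.

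With Imatinib alone, Cyp1a1 rose by 3.54 ± 0.66 over untreated lungs (adjusted p = 0.0437) and Pax5 by 1.62, with 16 genes higher and 55 lower in all. Of 15 heat shock genes 6 fell when adjusted over the list alone and 0 over all genes (adjusted p of the list = 3.22e-06, and 0.174 with an estimated correlation). The B cell and T and NK cell lists were higher, with 1 of 23 and 0 of 32 members past the threshold (adjusted p = 3.22e-06 and 0.000186, and 0.767 and 0.966 with an estimated correlation). The other largest rises were in Olfr225, Il20, Hpgds and Gpr34, and the largest falls in Olfr888, at background with Imatinib and at least 4.94-fold lower, Olfr1305, Cyp4x1, Olfr1093 and Aanat. Without IR 1, which enters this comparison through the shared spread alone, 40 genes were higher and 91 lower; the count was 26 without Imatinib 1, 18 without Imatinib 2 and 117 without untreated 2. None of the 11 named genes that passed with Imatinib kept its call without each array of these groups in turn, and the T and NK cell list had an adjusted p of 0.164 without Imatinib 1. With Su alone, C1s2, at background in untreated lungs, was at least 42.1-fold higher (adjusted p = 5.79e-07) and the atrial peptide Nppa lower (-3.34). Ahrr, the repressor of the aryl hydrocarbon receptor, at background in untreated lungs, was at least 1.45-fold higher, and Cyp1a1 was at 2.35 without passing (adjusted p = 0.0746). Of 15 heat shock genes 7 fell (10 adjusted over the list alone), with Hspa1a at -1.46, Hsph1 at -0.86 and Hspb1 at -0.74 (adjusted p = 1.5e-09, and 0.0334 with an estimated correlation). Spag11a, Zfp982, Fam167b and Necab3 were the next highest, and Fthl17e, Olfr888, Olfr684 and Apon the other lowest. In all, 164 genes were higher and 382 lower with Su, 455 and 700 without IR 1, and the count was 89 without Su 1, 98 without Su 2, 352 without untreated 1 and 272 without untreated 2; with normexp background correction 143 were higher and 157 lower. Among the 14 named genes that passed, C1s2 kept its call whichever array of the groups compared was left out.

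With Ly+Imatinib and no irradiation, Cfd, an adipocyte protease, was lower than in untreated lungs, at -4.04 ± 0.92, with Adipoq at -3.21, Car3 at -3.24 and the airway secretory genes Reg3g at -4.35 and Scgb3a1 at -3.14. Cfd, Adipoq, Car3, Reg3g and Scgb3a1 were at -1.93, -1.59, -1.73, -2.56 and -1.69 without Ly+Imatinib 1, where none passed (adjusted p of 0.3 to 0.501), and -6.14, -4.83, -4.74, -6.14 and -4.60 without Ly+Imatinib 2; Adipoq was above background on 1 Ly+Imatinib array. The adipose and club cell lists had 3 of 12 and 3 of 20 members lower (adjusted p = 7.9e-07 and 1.56e-09, and 0.0974 and 0.23 with an estimated correlation), and the cardiac muscle list 1 of 18 (adjusted p = 1.07e-06, and 0.423 with an estimated correlation). B cell genes rose in 5 of 23 cases (14 adjusted over the list alone), with Pax5 at 2.56 (adjusted p = 7.07e-09, and 0.413 with an estimated correlation). Heat shock genes fell in 5 of 15 cases (9 adjusted over the list alone) and glucocorticoid response genes in 2 of 14 (9 alone), with adjusted p = 4.25e-10 and 4.31e-09, and 0.0269 and 0.043 with an estimated correlation. Olfr64, Slc2a2, Pate5, Gbx2 and Olfr283 were the highest and Olfr888 was among the lowest; of all genes 367 were higher and 139 lower, 688 and 359 without IR 1, and the count was 25 without Ly+Imatinib 1, 254 without Ly+Imatinib 2, 279 without untreated 1 and 228 without untreated 2. With quantile normalization 215 were higher and 138 lower, and with normexp background correction 163 and 149. Among the 12 named genes that passed, Pax5 kept its call whichever array of the groups compared was left out. With Ly+Su and no irradiation, Rab27a fell (-2.60 ± 0.18; adjusted p = 1.84e-05), as did Fam107a, a stress-induced actin-binding protein (-2.18), and the collagen prolyl hydroxylase subunit P4ha1 (-0.78); Ahrr, at background in untreated lungs, was at least 1.48-fold higher. Heat shock genes fell in 5 of 15 cases (10 adjusted over the list alone), with Hspb1 at -1.21 and Hsp90aa1 at -0.75 (adjusted p = 7.73e-16, and 0.0041 with an estimated correlation). The T and NK cell list was higher, with 0 members past the threshold over all genes and 7 adjusted over the list alone (adjusted p = 4.38e-10, and 0.367 with an estimated correlation). Khdrbs2, Pate5, F9, Olfr738 and Yipf7 were the highest, and Olfr888, Hsd3b4 and Mc4r were also among the lowest. In all 75 genes were higher and 66 lower, 205 and 171 without IR 1, and the count was 52 without Ly+Su 1 and 75 without Ly+Su 2. With quantile normalization 71 were higher and 79 lower, with normexp background correction 56 and 65, and on genes above background on all 24 arrays 14 and 41. Of the 15 genes reported throughout, 0 passed in limma with Ly, Su, Ly+Imatinib or Ly+Su alone, and Cyp1a1 passed with Imatinib. Among the 14 named genes that passed, 5 kept their call whichever array of the groups compared was left out (Fam107a, Hsp90aa1, Hspb1, P4ha1 and Rab27a).

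The irradiated combinations were compared with their single agents. Against IR+Ly, the addition of Imatinib went with a rise of Cyp1a1 by 3.11 ± 0.66, Tfap2e by 3.30 and Top2a by 1.48. Tfap2e was at 2.65 without IR+Ly 1 and 3.95 without IR+Ly 2. The clock genes Dbp (-1.86) and Per2 (-1.45) and Tpm2, a muscle tropomyosin (-1.42), fell. Heat shock genes fell in 6 of 15 cases and clock genes in 4 of 17, and proliferation genes rose in 3 of 30 (19 adjusted over the list alone). Their adjusted p was 4.57e-10, 0.017 and 4.57e-10, and 0.0301, 0.708 and 0.908 with an estimated correlation. Olfr131, Olfr1232 and Npr3 were others of the largest size. Prl3b1 and Erbb3, which ranked with them, were at 1.75 and -0.58 without IR+Ly+Imatinib 1, where neither passed, and at 4.93 and -2.69 without IR+Ly+Imatinib 2. In all 554 genes were higher and 133 lower (882 and 314 without IR 1), and the count was 220 without IR+Ly 1, 313 without IR+Ly 2 and 247 without IR+Ly+Imatinib 1; with quantile normalization 273 were higher and 153 lower, and with normexp background correction 169 and 103. Taking the 11 named genes past the threshold, 2 kept their call whichever array of the groups compared was left out (Olfr1232 and Tpm2). The clock list had an adjusted p of 0.0624 without IR+Ly 2. Against IR+Imatinib, the addition of Ly went with 293 changed genes, 256 higher and 37 lower, of which 69 were above background on all 4 arrays. Olfr1232, Olfr434, Olfr1211, Olfr788 and Gast were the highest and Spertl, Olfr1012, Nlrp14, Bard1 and Scn11a the lowest, each at background in 1 of the groups. The proliferation list was higher with 0 of 30 members past the threshold, over all genes and adjusted over the list alone, and the adipose list lower with 0 of 12 (3 adjusted over the list alone). Their adjusted p was 1.23e-11 and 0.00193, and 0.572 and 0.572 with an estimated correlation, and the count was 151 without IR+Ly+Imatinib 1 and 674 without IR+Ly+Imatinib 2. None of the 15 genes reported throughout passed in limma in this comparison. Taking the 10 named genes past the threshold, 6 kept their call whichever array of the groups compared was left out (Bard1, Olfr1012, Olfr1232, Olfr434, Olfr788 and Spertl). The adipose list had an adjusted p of 0.375 without IR+Imatinib 1.

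With Su added to IR+Ly, 7 of 15 heat shock genes fell (10 adjusted over the list alone), with Hsph1 at -1.15 and Hspb1 at -0.83 (adjusted p = 3.74e-11, and 0.0182 with an estimated correlation). The collagen and p53 lists were lower with 0 members past the threshold (adjusted p = 0.000246 and 7.29e-05, and 0.696 and 0.638 with an estimated correlation). Tnfsf12, at background with IR+Ly, was at least 2.29-fold higher, with Olfr1316, Olfr1232, Smg8 and Olfr519 next; Ptgdr, Tdrd9, Tpbpb, Spertl and Fam107a were the lowest. Spertl was above background on 2 of the 24 arrays, both of them IR+Imatinib, so that its difference here lies between background levels. With normexp background correction Spertl was at 0.027. In all 577 genes were higher and 68 lower (918 and 219 without IR 1), and the count was 327 without IR+Ly 1, 263 without IR+Ly 2, 147 without IR+Ly+Su 1 and 181 without IR+Ly+Su 2; with normexp background correction 162 were higher and 41 lower, and with no filter on background 1049 were higher and 2496 lower. Of the 12 genes named that passed, 5 kept their call whichever array of the groups compared was left out (Hspb1, Olfr1232, Olfr1316, Olfr519 and Tnfsf12). Against IR+Su, adding Ly gave 651 higher and 16 lower genes, with 149 of the 667 above background on all 4 arrays; 475 were above background on both IR+Ly+Su arrays and on neither IR+Su array. With no filter on background 949 were higher and 2007 lower. Olfr1232, Olfr1316, Slc2a2, Ugt3a2 and Olfr434 were the highest and Unc13c, Ptgdr, Slc15a1, Ddx3y and Il20 the lowest. Ddx3y, on the Y chromosome, had a log2 level of -8.84 ± 0.14 against -5.98 ± 0.98 (mean ± SD, n = 2), near background in both groups. No list passed, and the count was 229 without IR+Ly+Su 1, 346 without IR+Ly+Su 2, 349 without IR+Su 1 and 307 without IR+Su 2. Taking the 10 named genes past the threshold, 4 kept their call whichever array of the groups compared was left out (Olfr1232, Olfr1316, Olfr434 and Ugt3a2). Between IR+Imatinib and IR+Su, within slide 5, 16 genes were higher and 0 lower with Imatinib (1765 at an unadjusted p under 0.05 in limma), among them H1f6, Olfr1012, Spertl, Olfr846 and Nxf2, all at background with IR+Su. The collagen and heat shock lists were higher with Imatinib than with Su and the B cell, T and NK cell and cardiac muscle lists lower. Their adjusted p was 1.18e-09, 2.23e-06, 2.87e-17, 1.92e-12 and 2.44e-08, and 0.361, 0.197, 0.249, 0.361 and 0.361 with an estimated correlation; over all genes 0 of their members passed in limma, and adjusted over the list alone 19 of 23 B cell genes were lower. The count was 457 without IR+Imatinib 1 and 9 without IR+Su 2, and with quantile normalization 6 genes were higher and 1 lower. Of the 15 genes reported throughout, 0 passed in limma between IR+Imatinib and IR+Su, 0 between IR+Ly+Su and IR+Ly, and 0 between IR+Ly+Su and IR+Su. Of the 5 genes named that passed, 3 kept their call whichever array of the groups compared was left out (H1f6, Olfr1012 and Spertl).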

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

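Chosen only after the result was seen were the tests given here of slides, of background, of array IR 1 and of the sample RNA and response of that array; the interaction, its list tests and the count over splits of the 24 arrays were planned. The results named here were picked because a test of the difference between drug arms passed. The irradiation difference varied between the 6 drug arms for 220 genes. The 10 smallest adjusted p were 0.000151 for Cep20, 0.000186 for Tnfsf12, 0.000191 for C1s2 and 0.000251 for Itga10 and Rab27a. Next were 0.000421 for Spertl and Tlx2, 0.000684 for Kcne3, 0.00188 for Mc4r and 0.00196 for Slc45a1. By list, against no drug, the collagen shift with irradiation was smaller in the Ly arm (adjusted p = 0.00076), the Su arm (0.00874) and the Ly+Su arm (0.000823). The inflammatory shift was smaller in the Ly (1.61e-14), Imatinib (3.5e-07), Su (0.00874), Ly+Imatinib (0.00331) and Ly+Su (4.12e-07) arms. The macrophage shift was smaller in the Ly (1.39e-10), Imatinib (0.000345), Ly+Imatinib (0.000741) and Ly+Su (0.000293) arms. None of these list calls held with an estimated correlation, where 0 of 185 passed in camera. Each arm was set against the same IR and untreated arrays, so that calls that recur over arms are not independent.

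For the interaction, a level that a slide adds to all its arrays cancels between arms that share both slides, and 22 genes passed there, Rab27a and Pax5 among them, which argues against slides for those genes. Cep20, Tnfsf12, Tlx2, Kcne3, Mc4r and Slc45a1, named above for their small p, did not pass there. Of the 220 genes 156 passed with and without IR 1, and 112 were above background on all 24 arrays, so that neither IR 1 nor the lower background on slide 6 could account for the whole. Between the pairs of slides, each with its own drugs, 533 genes passed, and there slides cannot be told apart from drugs. A difference in the response to irradiation with the drugs stays open as untested. Unirradiated arrays hold part of the difference for Pax5 and C1s2 (Su arm) and most for Rab27a (Ly+Su arm).

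For the averaged irradiation difference, 1 of 100 splits of the 24 arrays into 12 and 12, the real one, gave as many genes. It gave 5863 with drug arm as a term, against at most 1943 in the other splits. Those were drawn over single arrays, without keeping slides or groups together, while the real one keeps both whole. They therefore cannot exclude a chance difference between slides. IR 1 alone is argued against, since 7743 genes passed without it. Of the 10 splits of the 6 slides into 3 and 3, which are too few for a share under 0.05, the real one gave 4739 genes and the highest other, slides 1, 2 and 4 against 3, 5 and 6, gave 3841. Irradiation and slide cannot be told apart, since no slide holds both conditions.

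For array IR 1, the spike-in probes lay -4.95 SD from the other 23 arrays, which is consistent with another amount of labelled sample RNA. A stronger response of that animal stays open: its response score differed from that of IR 2 by -0.016, with a replicate SD of 0.16 pooled over the other groups, while its collagen and inflammatory lists were higher by 0.64 and 0.81. Its mast cell list was higher by 2.60, against at most 1.49 between replicates of the other groups. Leaving out either IR array moved the counts against IR, down without IR 1 and up without IR 2, with 161 and 8631 genes for irradiated against untreated.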

How the results depend on the processing

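Chosen only after the data were seen were the common floor, the slide means, the interaction split into tests within and between slides, which is the form its slide block took, and leaving out IR 1 where IR is not compared; the other alternatives were planned. Values taken from the deposited series table and a replicate block moved no count by more than 1.5 times; the replicate block gave 3344 genes for irradiated against untreated, 6913 for the averaged comparison, 257 for IR+Ly against IR and 190 for the interaction. Counts that moved, and for which the cause was not tested unless stated, follow by alternative. With normexp background correction and quantile normalization they were 1070 for IR+Imatinib against IR, 1930 for IR+Ly+Imatinib against IR, 3776 for IR+Ly+Su against IR, 6 for Ly against untreated, 17 for Imatinib against untreated, 300 for Su against untreated, 312 for Ly+Imatinib against untreated, 272 for IR+Ly+Imatinib against IR+Ly, 145 for IR+Ly+Imatinib against IR+Imatinib, 203 for IR+Ly+Su against IR+Ly, 206 for IR+Ly+Su against IR+Su, 3 for IR+Imatinib against IR+Su and 98 for the interaction. With quantile normalization they were 96 for IR+Ly against IR, 1023 for IR+Imatinib against IR, 1908 for IR+Ly+Imatinib against IR, 3775 for IR+Ly+Su against IR, 8 for Ly against untreated, 426 for IR+Ly+Imatinib against IR+Ly, 332 for IR+Ly+Su against IR+Ly, 7 for IR+Imatinib against IR+Su and 120 for the interaction. With no filter on background they were 1829 for irradiated against untreated, 18 for IR+Ly against IR, 1605 for IR+Imatinib against IR, 28 for Imatinib against untreated, 321 for Su against untreated, 248 for Ly+Imatinib against untreated, 81 for Ly+Su against untreated, 3545 for IR+Ly+Su against IR+Ly and 2956 for IR+Ly+Su against IR+Su; the median of all genes then lay at -0.11 for irradiated against untreated. Tested on genes above background on all 24 arrays, which are fewer, they were 0 for Ly against untreated, 11 for Imatinib against untreated, 322 for Su against untreated, 224 for Ly+Imatinib against untreated, 55 for Ly+Su against untreated, 282 for IR+Ly+Imatinib against IR+Ly, 6 for IR+Ly+Imatinib against IR+Imatinib, 162 for IR+Ly+Su against IR+Ly, 32 for IR+Ly+Su against IR+Su, 0 for IR+Imatinib against IR+Su and 112 for the interaction. With every probe tested they were 288 for IR+Ly against IR, 4388 for IR+Imatinib against IR and 36 for Imatinib against untreated. With all values raised to a common floor they were 5 for Ly against untreated, 337 for IR+Ly+Su against IR+Su, 38 for IR+Imatinib against IR+Su and 381 for the interaction. When limma was fitted to the groups compared alone, with fewer arrays to estimate the spread, it called 1170 genes between IR+Ly+Su and IR+Su and 0 in 14 of the 16 comparisons of 2 groups, with 800 to 4516 genes at an unadjusted p under 0.05; for the averaged comparison and the interaction that fit is the one reported. With slides as a block, the averaged comparison gave 3233 genes and the interaction, tested within slides, 22. On slide means, which leave 6 values, they were 1 for the averaged comparison and 19 for list tests of the averaged comparison. For comparisons across slides no slide term can be fitted. With an estimated correlation they were 6 for list tests. Named genes and lists that lost their call numbered 84 with normexp background correction, 62 with quantile normalization, 52 with no filter and 91 with a common floor. Fitted to the groups compared alone, 266 calls of named genes were lost.

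Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave counts of 161 to 8631 for irradiated against untreated, 5588 to 8433 for the averaged comparison, 0 to 38 for Ly against untreated, 18 to 131 for Imatinib against untreated, 89 to 1155 for Su against untreated, 25 to 1047 for Ly+Imatinib against untreated, 52 to 376 for Ly+Su against untreated, 98 to 5416 for the interaction, 168 to 205 for list tests, 15 to 7769 for IR+Ly against IR, 274 to 9052 for IR+Imatinib against IR, 1505 to 9536 for IR+Su against IR, 1345 to 8977 for IR+Ly+Imatinib against IR, 1508 to 10006 for IR+Ly+Su against IR, 220 to 1196 for IR+Ly+Imatinib against IR+Ly, 151 to 674 for IR+Ly+Imatinib against IR+Imatinib, 147 to 1137 for IR+Ly+Su against IR+Ly, 229 to 707 for IR+Ly+Su against IR+Su and 9 to 457 for IR+Imatinib against IR+Su. Of 326 calls of named genes, summed over comparisons, 130 were kept whichever array was left out, 196 were lost at least once and 0 reversed. The irradiation response score moved by more than the SD between replicates of the same arm to 0.57 for Imatinib, 0.48 for Su, 0.75 for Ly+Imatinib and 0.51 for Ly+Su with normexp background correction, 0.55 for no drug, 0.70 for Su and 0.76 for Ly+Su with quantile normalization, 0.57 for Imatinib, 1.30 for Ly+Imatinib and 0.93 for Ly+Su with no filter and 0.71 for Su, 0.95 for Ly+Imatinib and 0.69 for Ly+Su on genes above background on all arrays. Cases in which the direction turned, beside the proliferation list against IR given above, include these. Spertl, at background in both groups, turned between IR+Ly+Su and IR+Ly, to 0.027 with normexp background correction. The test of the collagen list, not past the threshold, turned between IR+Ly+Imatinib and IR, at a mean of -0.037 with normexp background correction, -0.080 with quantile normalization, 0.16 without IR 1 and 0.30 without IR+Ly+Imatinib 2, and between IR+Imatinib and IR, at 0.085 without IR+Imatinib 1; leaving out 1 array its mean ran from -0.61 to 0.30 and from -0.76 to 0.085. The neutrophil list with Ly alone turned to -0.79 without Ly 1, in a range of -0.79 to 2.16. Signal over background limits what calls of dim genes show: between IR+Ly+Su and IR+Su, 149 of the 667 calls were on genes above background on all 4 arrays, against 84.4% of tested genes. In the simulated data above, limma found 22 of 50 genes at a log2 change of 1 and 44 of 50 at 2. This was between irradiated and untreated, where it also called 10 unchanged genes. These counts do not cover slides, outlying arrays or correlated genes.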

Other observations

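No test of a hypothesis is given here; the choice of lists described was made after their values were seen. The heat shock and unfolded protein list, which holds cytosolic and endoplasmic reticulum chaperones, was called in 13 of 17 comparisons, as higher between IR+Imatinib and IR+Su and as lower in the others, in 5 of them with an estimated correlation. Its mean log2 level without irradiation was 3.18 in untreated lungs and 3.23 with Ly, and 2.89 with Imatinib, 2.67 with Su, 2.68 with Ly+Imatinib and 2.60 with Ly+Su. In irradiated lungs it was 3.19 without drug, 3.04 with Ly, 2.71 with Imatinib, 2.37 with Su, 2.55 with Ly+Imatinib and 2.52 with Ly+Su. The SD between the 2 arrays of a group was at most 0.20. The means of 3.04 to 3.23, in the untreated, Ly, IR and IR+Ly groups, came from slides 1 and 4, and all lower means from other slides. Drug and slide therefore cannot be told apart in these levels, except between groups that share a slide.

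Markers of tissues beside the lung varied between arrays of the same group. The cardiac muscle list had a mean of -3.10 on Ly 1 and -1.65 on Ly 2, -3.75 on Ly+Imatinib 1 and -1.43 on Ly+Imatinib 2, and -0.81 and -0.47 on the untreated arrays. The adipose list had a mean of -1.10 with Ly+Imatinib and -1.29 with IR+Ly+Imatinib, against 0.23 in untreated and -0.16 in irradiated lungs. Alveolar type II cell genes were called lower in 3 of 17 comparisons, with a smallest adjusted p of 0.00636. The lists of AhR targets, the PDGF family and kinases blocked by imatinib, TGF-beta ligands and receptors, erythroid cells, fatty acid synthesis, fibroblasts, immediate early genes, sex-linked genes and skeletal muscle were called in 0 of 17 comparisons with camera, with smallest adjusted p of 0.0896, 0.329, 0.324, 0.058, 0.0505, 0.133, 0.0704, 0.0642 and 0.139.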
